A study of Homo sapiens with 12 samples.

How the data were processed

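RNA of MCF-7 cells described as constitutively active IKKβ cells was hybridized to 12 one-colour Affymetrix arrays after 3′ IVT labelling with biotin, 3 arrays for each of Vehicle, E2, Dox and E2+Dox. The deposited values are log2 probe set signals that the authors normalized between arrays, and the processing notes name RMA and Partek 6.6 without giving their roles, order or settings. The values ran from about 3 to 15 with nearly the same quartiles on every array, so they were used as deposited, without another logarithm or normalization. The labels give the treatment time of 72 h and the 48 h in hormone-stripped medium, but no doses.

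The array annotation lists 49395 probe sets, of which 44994 carry a single gene symbol, 1832 several and 2569 none, 102 of the last being controls. Probe sets with a single symbol were kept, and 44967 of them were found in the reference by Entrez number, with 0 symbols updated. Each of the 18132 genes was represented by its brightest probe set over all arrays, and a gene was tested when at least 3 of the 12 arrays reached the 40th percentile of their own array, which left 12482 genes. Groups were taken from the labels. A model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (jsonlite 2.0.0 read the labels), with variances moderated across genes (prior degrees of freedom 4.81, residual 8), for 5 differences between groups and the interaction of E2 and Dox. Limma's p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. The same adjustment was also made over each gene list alone. Replicate numbers did not pair the samples: of 18 same-number pairs between groups 1 had a residual correlation over 0.1, and 0 arrays correlated best with their own number in every other group.

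A set of 32 gene lists with 678 genes was fixed before the data were examined, and 533 of these genes were tested. They cover NF-κB targets and pathway components, genes under joint control, estrogen-induced and estrogen-repressed genes, luminal, basal and mesenchymal genes, TGF-β targets, matrix genes, replication, mitosis, growth arrest, interferon response, antigen presentation, acute phase genes, TNF receptors, apoptosis, growth factors, p53, amino acid stress, unfolded proteins, cholesterol, glycolysis, oxidative phosphorylation, mitochondrial translation, ribosome biogenesis, core histones, housekeeping genes and markers of fibroblasts, blood cells and endothelium. Each list with at least 3 tested genes was compared with all other genes by camera with a preset correlation of 0.01 between genes, and again with an estimated correlation, camera on ranks and fry. Camera p-values were adjusted over the lists of a comparison.

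Genes named in the text follow a rule set before the data were examined. For each comparison it takes the 10 largest rises and 10 largest falls among genes past the threshold whose 3 arrays of a group all lie above the 3 of the other group, a condition not asked of the interaction. For each list it takes up to 4 members with the largest change past the threshold, or the member with the largest change where none passes. It always takes IKBKB, ESR1, PGR, TFF1, GREB1, MKI67, CDKN1A, NFKBIA, TNFAIP3, BIRC3, CXCL8, ABCG2, PTGES, PHLDA1, CD44, VIM and CDH1, but BIRC3 has no probe set with a single symbol and so no value.

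Alternatives covered the filter on dim probe sets, the choice of probe set, scaling between arrays, the variance model, array weights, the arrays in the fit, the replicate number as a block, the thresholds, the set test, the correlation measure and leaving out each array in turn. The 3′ to 5′ difference of ACTB as a covariate, the GC-rich background as a covariate and a mean level of at least 7 were added after the data had been seen. The procedure was tested on simulated data with 200 changed genes: changes of 1 and 2 on the log2 scale were all recovered, those of 0.5 in 92.8% to 100% of cases for differences between groups and in 71.4% for the interaction, with 7 to 14 false calls. Camera called the list that was moved in 20 of 20 simulations and made 1 call of another list. Noise in these simulations was drawn independently for each gene, so they do not test camera on correlated genes. For mitotic genes the estimated correlation on the real arrays was 0.43 in E2 against Vehicle. Overlaps expected without effects came from 20 simulations.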

Results

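Gene expression was measured on 12 Affymetrix arrays in MCF-7 cells, an estrogen receptor-positive breast cancer line, in a derivative described by its labels as constitutively active IKKβ cells. IKKβ, encoded by IKBKB, is the kinase that marks the NF-κB inhibitor IκBα for degradation and so frees NF-κB to enter the nucleus. Cells were kept for 48 h in hormone-stripped medium and then treated for 72 h with vehicle, estrogen (E2), doxycycline (Dox) or both (E2+Dox), with 3 samples in each of the 4 groups. The labels do not say whether the 3 samples of a group came from separate cultures, so the adjusted p-values measure only the spread between these samples. The labels do not say what Dox does in these cells, and the series holds no cells without the active kinase, so effects of Dox that do not pass through IKBKB have no control here. Each change below is the log2 difference between group means ± its standard error in the limma fit, with n = 3 per group, and every change given with a verb such as rose or fell passed an adjusted p of 0.05. The values carry no detection calls, so a gene under the 40th percentile of all 3 arrays of a group (5.36 to 5.47) is not known to be above background there. This held for 31 of the 199 differences looked up for genes of the text, and a change against such a group is given as a bound, with the percentile in place of a dimmer signal. A change that involves a group within 1 log2 unit of 14.76, the lowest of the highest signals of the arrays, is also given as a bound, because of saturation. Rankings and list medians use the measured signals. Of 18132 genes with a probe set, 12482 (68.8%) were bright enough to be tested. Arrays have no read depth, and the number of arrays limits the precision. The labels name no genome build, so genes are identified by symbol and Entrez number without positions.

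The 4 groups separated on the first principal components of the tested genes, which held 51.2% and 38.1% of the variance. Correlations between arrays of the same group lay between 0.997 and 0.998, and the highest between arrays of different groups was 0.989. Median log2 signals of the arrays ranged from 6.17 to 6.25. The difference between the 3′ and 5′ probe sets of ACTB, a measure of RNA integrity in which higher values point to shorter RNA, was 1.01 ± 0.12 (log2, SD, n = 3) in Vehicle, 0.65 ± 0.01 in E2, 0.89 ± 0.15 in Dox and 0.74 ± 0.05 in E2+Dox. The background of GC-rich control probe sets was 7.03 ± 0.09 (SD, n = 3) in Vehicle and 7.26 ± 0.03 in E2+Dox. By an exact two-sided permutation test, the p for E2 against Vehicle in the ACTB difference and for E2+Dox against Vehicle in the background was 0.1 each, the smallest that 3 against 3 samples can give.

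**Figure D1:**
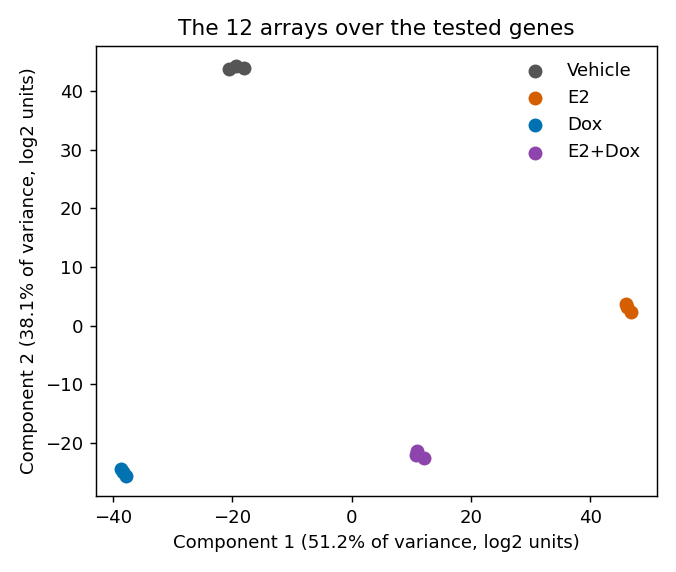
Principal components of the 12 arrays over the 12482 tested genes; each point is an array, coloured by group, and both axes are in log2 units. Arrays of a group lie together, with E2 and Dox at opposite ends of component 1 (51.2% of the variance) and Vehicle apart from the other groups on component 2 (38.1%).

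Estrogen alone raised the classical targets of its receptor and the genes of DNA replication, mitosis and ribosome production, and it lowered most of the known estrogen-repressed genes. The comparison of E2 with Vehicle asks what 72 h of estrogen changed in hormone-deprived cells without Dox. Of 34 tested estrogen-induced genes, 33 rose, with a median log2 change of 1.64. PGR, the progesterone receptor (Entrez gene 5241), rose by 4.50 ± 0.09 (adjusted p = 2.26e-13), the transcription factor EGR3 (Entrez gene 1960) by 4.86 ± 0.09, SUSD3 (Entrez gene 203328) by 4.49 ± 0.05 and GREB1, a coactivator of the estrogen receptor (Entrez gene 9687), by 3.06 ± 0.11. TFF1, a secreted trefoil peptide (Entrez gene 7031), rose by at least 1.59. The camera test called the list higher with adjusted p = 1.33e-16, and with adjusted p = 0.0189 with an estimated correlation, the only one of the 11 list calls in this comparison that held with it. Of 11 estrogen-repressed genes 9 fell, with a median of -2.18 (adjusted p = 6.14e-05, and adjusted p = 0.101 with an estimated correlation). Among them were the adaptor BLNK (-4.58 ± 0.07), the p53-induced stress gene TP53INP1 (-3.75 ± 0.07), the PI3K inhibitor PIK3IP1 (-3.47 ± 0.07) and CCNG2, an atypical cyclin linked to arrest (-2.64 ± 0.13). ESR1, the estrogen receptor itself (Entrez gene 2099), fell, with a change of -1.04 ± 0.06 (adjusted p = 3.45e-09).

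Most tested genes of DNA replication, mitosis, ribosome biogenesis and mitochondrial translation rose with E2. Each of the 34 tested DNA replication genes rose (median 1.11, adjusted p = 3.26e-15, and adjusted p = 0.0718 with an estimated correlation), among them the replication initiator MCM10 (2.11 ± 0.07) and CDC45 (1.91 ± 0.07). So did each of the 34 mitotic genes (median 1.16, adjusted p = 4.88e-14, and adjusted p = 0.215 with an estimated correlation), including CDC20 (2.12 ± 0.08), which activates the anaphase-promoting complex, and MKI67, the gene of the proliferation marker Ki-67 (Entrez gene 4288), at 0.95 ± 0.08. All 24 ribosome biogenesis genes rose (median 1.17, adjusted p = 1.11e-11, and adjusted p = 0.0984 with an estimated correlation), led by NOP16 (2.07 ± 0.06). Similarly, 20 of 22 mitochondrial translation genes rose (median 0.64, adjusted p = 3.43e-07, and adjusted p = 0.169 with an estimated correlation), led by MRPL12 (1.29 ± 0.08). Of 15 growth arrest genes 8 fell, among them the cyclin-dependent kinase inhibitors CDKN1C (-2.35 ± 0.10) and CDKN1A (Entrez gene 1026, -2.15 ± 0.06). The median was -0.72 (adjusted p = 0.0333, and adjusted p = 0.335 with an estimated correlation). TGF-β and BMP targets had 10 of 13 members lower (median -0.97, adjusted p = 0.00107, and adjusted p = 0.0984 with an estimated correlation), such as TGFB3 (-2.72 ± 0.08), ID3 (-2.09 ± 0.07) and ID1 (-2.01 ± 0.08). Core histone genes had 9 of 13 lower and 2 higher (median -1.28, adjusted p = 0.0185, and adjusted p = 0.215 with an estimated correlation), with H4C8 (-2.18 ± 0.15) and H2BC21 (-2.17 ± 0.06) falling most. The fixed list of that name also holds genes of linker histones and of histone variants. Cholesterol synthesis genes had 11 of 17 higher (median 0.48, adjusted p = 0.0293, and adjusted p = 0.338 with an estimated correlation), including HMGCS1 (1.32 ± 0.06), while HSD17B7 fell (-1.24 ± 0.07). Oxidative phosphorylation genes had 19 of 28 higher with a small median of 0.22 (adjusted p = 0.00416, and adjusted p = 0.338 with an estimated correlation). This median turned to -0.0108 when arrays were shifted to the same mean of housekeeping genes.

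Outside the lists, the largest rises were FGFBP2, a fibroblast growth factor-binding protein (Entrez gene 83888), up by at least 6.00, the serine protease TMPRSS3 (at least 3.24), the matrix protein MGP (4.48 ± 0.06), the protease PRSS23 (4.35 ± 0.05) and the Notch effector HEY2 (4.30 ± 0.14). The largest falls were IL1R1, the receptor of interleukin-1 (Entrez gene 3554), at -5.85 or lower, the basement membrane protein HMCN1 (-3.61 or lower), the cell cycle kinase CDK6 (Entrez gene 1021, -4.13 ± 0.06) and RPRM (-4.12 ± 0.14). The rule that named these genes required the 3 E2 samples to lie apart from the 3 Vehicle samples, so this separation is no further support. NF-κB targets were not called as a list (5 higher and 13 lower of 31, median -0.16, adjusted p = 0.178), although REL (-2.23 ± 0.10), IRF1 (-1.82 ± 0.09) and the inhibitors NFKBIA (-0.66 ± 0.05) and TNFAIP3 (-0.16 or lower) fell. IKBKB (-0.07, adjusted p = 0.646) did not pass in the probe set used, and nor did CXCL8 (adjusted p = 0.162), whose change has no known size because E2 lay under the 40th percentile. Of the 11 probe sets of IKBKB, however, 4 fell with E2 and 0 rose, and the 3 that Dox did not raise stood at -0.72 to -0.16. Without Vehicle replicate 1 CXCL8 passed, and without Vehicle replicate 2 the sign for IKBKB was positive (0.033). VIM, an intermediate filament of mesenchymal cells, rose by 1.25 ± 0.10 and CD44, a cell surface adhesion receptor, by 1.20 ± 0.05, while CDH1, the gene of E-cadherin, fell (-0.73 ± 0.06). Of the drug transporter ABCG2, the prostaglandin synthase PTGES and PHLDA1, which estrogen and NF-κB are reported to control jointly, ABCG2 (-0.84 ± 0.06) and PHLDA1 (-1.19 or lower) fell, and PTGES stood at 0.29 (adjusted p = 0.0229). The call of PTGES was lost without E2 replicate 2 (0.22), Vehicle replicate 1 (0.19) or Vehicle replicate 2 (0.28).

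In all, 8450 of 12482 genes (67.7%) changed in limma, 3915 higher and 4535 lower, and 678 and 877 of these changed by at least 2-fold. The E2 and Vehicle samples did not overlap in 9006 genes (72.2%), where 10% would do so by chance. Among changed genes 46.3% were higher, and 25.7% after shifting the arrays to the same mean of housekeeping genes. That shift moved the median change of all genes to -0.23, so the even split of directions depends on the scaling. Between the alternatives, including left-out arrays and other choices of probe set, some measured values moved by over 1.5 times. These were EGR3 (1.37 to 5.09), TP53INP1 (-3.98 to -1.75), PIK3IP1 (-3.70 to -1.60), ESR1 (-1.27 to -0.54), H2BC21 (-2.39 to -0.83), TMPRSS3 (1.93 to 4.53) and MGP (2.44 to 4.53). So did IL1R1 (-6.65 to -3.38), IRF1 (-2.05 to -0.79), IKBKB (-0.33 to 0.22), CD44 (0.97 to 2.31), PHLDA1 (-1.68 to -0.84) and PTGES (0.060 to 1.72, adjusted p up to 0.6). List medians did so for mitochondrial translation (0.41 to 0.71), growth arrest (-0.94 to -0.23), TGF-β and BMP targets (-1.19 to -0.45), core histones (-1.51 to -0.57) and cholesterol synthesis (0.25 to 0.61). The calls of growth arrest genes (median -0.23, adjusted p = 0.132 with the ACTB difference, which itself separates E2 from Vehicle, as a covariate), core histone genes (adjusted p = 0.07 with the housekeeping shift) and oxidative phosphorylation genes (adjusted p = 0.0804 with that shift) did not hold under every alternative.

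Dox alone raised IKBKB itself, turned on NF-κB targets, acute phase genes, interferon response and antigen presentation genes, and lowered the genes of DNA replication and mitosis. The comparison of Dox with Vehicle asks what 72 h of Dox changed without estrogen. IKBKB (Entrez gene 3551) rose by 3.75 ± 0.12 (adjusted p = 1.62e-11), from a log2 signal of 6.28 ± 0.18 (SD, n = 3) to 10.03 ± 0.22. Of 31 tested NF-κB targets 25 rose and 2 fell, with a median of 1.78 (camera adjusted p = 9.97e-12, and adjusted p = 0.0108 with an estimated correlation). The monocyte chemoattractant CCL2 (Entrez gene 6347) rose by at least 5.56, the lymphotoxin LTB (Entrez gene 4050) by at least 5.95, the NF-κB inhibitor TNFAIP3 (Entrez gene 7128) by 5.46 ± 0.08 and the cytokine IL32 by 4.51 ± 0.11.

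Further NF-κB genes moved the same way: NFKBIA, the gene of IκBα (Entrez gene 4792), rose by 1.94 ± 0.05 and the chemokine CXCL8 (Entrez gene 3576) by 2.56 ± 0.14. Of the pathway's own components 8 of 14 rose, with a median of 0.20 (adjusted p = 0.0273, and adjusted p = 0.0979 with an estimated correlation), among them TRAF3 (2.11 ± 0.06), CYLD (1.77 ± 0.07) and IKBKE (1.60 ± 0.10), and the call was lost with the most variable probe set of each gene (median -0.014, adjusted p = 0.156). Of 11 IKBKB probe sets, 8 rose with Dox by 2.33 to 4.14. The other 3 stood at -0.30 to -0.17, and 2 of them passed as lower in Dox. The files do not say which part of the transcript each probe set reads. Acute phase and epithelial defence genes had 8 of 12 higher, with a median of 2.18 (adjusted p = 1.47e-05, and adjusted p = 0.0407 with an estimated correlation). Only 12 of its 23 genes were bright enough, and the median depended on the filter, from 0.046 with none to 5.90 with the strictest, while the call held throughout. These included the calprotectin subunits S100A9 (Entrez gene 6280) up by at least 8.14 and S100A8 (Entrez gene 6279) up by at least 7.39, and the complement gene CFB at 5.90 ± 0.11. Interferon response genes had 15 of 17 higher (median 0.88, adjusted p = 5.06e-06, and adjusted p = 0.0241 with an estimated correlation), such as ISG20 (2.92 ± 0.06) and the RNA sensor IFIH1 (2.25 ± 0.11). Antigen presentation genes had 11 of 14 higher (median 1.25, adjusted p = 2.37e-06, and adjusted p = 0.0241 with an estimated correlation), such as HLA-F (3.52 ± 0.13), HLA-B (3.15 ± 0.14), members of a family with similar sequences, and the immunoproteasome subunit PSMB9 (3.09 ± 0.08).

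**Figure D2:**
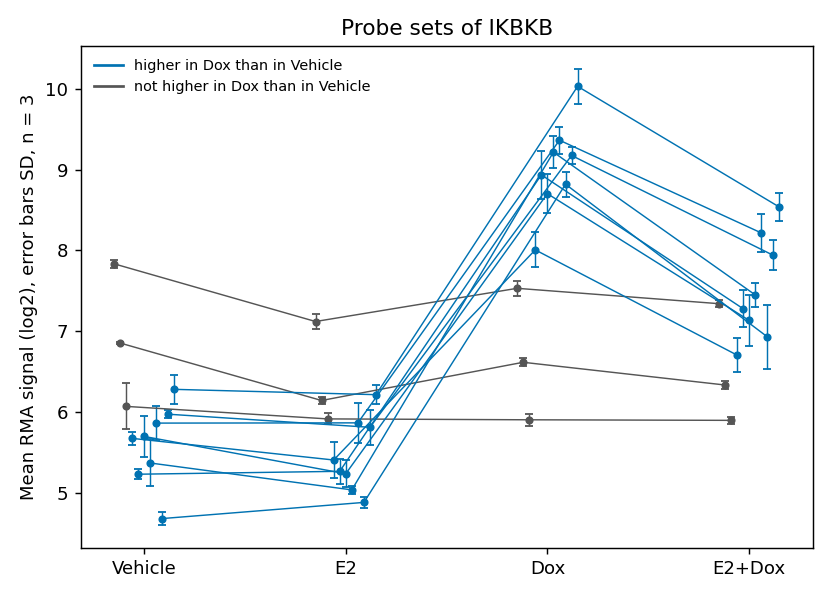
Mean RMA signal (log2) of each of the 11 IKBKB probe sets in the 4 groups, with error bars of 1 SD (n = 3). The 8 probe sets drawn in blue rose with Dox by 2.33 to 4.14 and lay lower in E2+Dox than in Dox by 1.15 to 1.89 log2 units. The 3 in grey stood at -0.30 to -0.17 with Dox, and 2 of them passed as lower.

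Proliferation genes fell with Dox. Each of the 34 mitotic genes fell (median -2.07, adjusted p = 5.72e-20, and adjusted p = 0.0895 with an estimated correlation), among them the kinetochore gene NDC80 (-2.76 ± 0.10), the spindle gene ASPM (-2.70 ± 0.07), topoisomerase TOP2A (-2.61 ± 0.06) and MKI67 (-2.17 ± 0.08). Of 34 DNA replication genes 31 fell (median -0.98, adjusted p = 7.26e-13, and adjusted p = 0.0407 with an estimated correlation), including the ribonucleotide reductase subunit RRM2 (-2.56 ± 0.05) and E2F8 (-2.60 ± 0.11). CDKN1A rose by 1.38 ± 0.06, while the growth arrest list, with THBS1 higher (1.62 ± 0.11) and CDKN1C lower (-1.92 ± 0.10), was not called (adjusted p = 0.967). Luminal epithelial genes had 11 of 18 lower (median -0.34, adjusted p = 0.00191, and adjusted p = 0.135 with an estimated correlation), among them ESR1 (-2.36 ± 0.06, adjusted p = 2.21e-12), SPDEF (-1.78 ± 0.08), KRT19 (-1.34 ± 0.06) and GATA3 (-1.12 or lower). Estrogen-induced genes went both ways, 14 higher and 17 lower of 34, and were not called (adjusted p = 0.967). GREB1 (-1.79 ± 0.11), CA12 (-1.66 ± 0.05) and PGR (-0.64 ± 0.09) fell, and ELOVL2 (1.28 ± 0.05), SLC7A5 (1.17 ± 0.06) and TFF1 (0.40 ± 0.06) rose. Estrogen-repressed genes had 9 of 11 lower (median -0.79, adjusted p = 0.00123, and adjusted p = 0.0995 with an estimated correlation), such as BLNK (-3.04 ± 0.07) and YPEL3 (-1.44 ± 0.06).

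Several smaller shifts followed. Matrix protease and adhesion genes had 11 of 17 higher (median 0.27, adjusted p = 0.00137, and adjusted p = 0.0671 with an estimated correlation), with the gelatinase MMP9 (2.35 ± 0.06) and the urokinase genes PLAU (at least 1.59) and PLAUR (1.78 ± 0.11) in front. TNF receptors had 7 of 8 higher (median 0.76, adjusted p = 0.00153, and adjusted p = 0.0995 with an estimated correlation), led by TNFRSF21 (3.77 ± 0.07). Amino acid stress genes had 14 of 21 higher (median 0.30, adjusted p = 0.00108, and adjusted p = 0.0979 with an estimated correlation), among them the cystine transporter SLC7A11 (2.89 ± 0.11) and asparagine synthetase ASNS (1.87 ± 0.05). Unfolded protein response genes had 12 of 17 higher (median 0.36, adjusted p = 0.0025, and adjusted p = 0.0407 with an estimated correlation), such as SDF2L1 (1.62 ± 0.06). Ribosome biogenesis genes had 21 of 24 higher (median 0.54, adjusted p = 1.57e-06, and adjusted p = 0.0995 with an estimated correlation), with NOP16 at 1.38 ± 0.06. Cholesterol synthesis genes had 12 of 17 higher (median 0.29, adjusted p = 0.022, and adjusted p = 0.297 with an estimated correlation). The same held for 12 of 22 mitochondrial translation genes (median 0.18, adjusted p = 0.00323, and adjusted p = 0.312 with an estimated correlation). Core histone genes stood at the threshold, with 8 of 13 lower, a median of -0.46 and adjusted p = 0.0499 (adjusted p = 0.236 with an estimated correlation). That call was lost without any of Dox replicate 3, E2 replicate 2 or 3, Vehicle replicate 3 or each of the 3 E2+Dox replicates, with adjusted p from 0.051 to 0.0587.

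Among other genes, the interleukin subunit EBI3 (at least 5.58), the steroid-metabolizing enzyme AKR1C1 (at least 3.42) and the transcription factor ETV5 (5.03 ± 0.07) were among the largest rises, and the chemokine receptor ACKR3 (-4.32 ± 0.12), the growth factor-binding protein IGFBP5 (-4.11 ± 0.08) and TXNIP (-3.40 ± 0.07) among the largest falls. PHLDA1 rose by 2.43 ± 0.11, PTGES rose by 0.42 ± 0.10 and ABCG2 fell (-0.87 ± 0.06). VIM fell by an amount that is not known, since Dox lay under the 40th percentile and Vehicle near it, and CD44 fell at its brightest probe set (-0.57 ± 0.05) but not at the mean of its probe sets (-0.0917). CDH1 did not pass (-0.14, adjusted p = 0.0718), although it passed without Vehicle replicate 1 at -0.19. Among blood cell markers ITGAM, an integrin of myeloid cells, rose by at least 2.66, and the list was not called (adjusted p = 0.275).

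In limma 7441 genes (59.6%) changed with Dox, 3561 higher and 3880 lower, of which 467 and 616 changed by at least 2-fold. Dox and Vehicle samples did not overlap in 7724 genes (61.9%, against 10% by chance). After the shift to the same mean of housekeeping genes, 35.8% of changed genes were higher, against 47.9% without it. Values that moved by over 1.5 times between the alternatives were those of IKBKB (2.44 to 3.88), CYLD (0.78 to 1.84), CFB (3.81 to 6.07), HLA-F (1.54 to 4.02), HLA-B (1.87 to 3.36), PSMB9 (1.97 to 3.17) and ITGAM (2.70 to 4.65). They also included ESR1 (-2.45 to -1.17), GREB1 (-1.88 to -0.77), PGR (-0.73 to -0.24), SLC7A5 (0.72 to 1.24), PTGES (0.32 to 2.49), CD44 (-0.66 to -0.036) and CDH1 (-0.34 to -0.066). Medians moved as much for NF-κB targets (0.86 with no filter, up to 2.22), interferon response (0.49 to 1.04), estrogen-repressed genes (-1 to -0.53) and matrix genes (0.18 to 0.93). The same was true of TNF receptors (0.42 to 0.84), amino acid stress (0.21 to 0.68) and mitochondrial translation (0.084 to 0.21).

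Adjusted over the list alone, the counts in these comparisons were the same as over all genes except for a few members. In E2 against Vehicle the NF-κB targets then had 4 higher and 12 lower, mitochondrial translation genes 21 higher, p53 targets 3 higher and growth factor genes 9 higher, and no blood cell marker passed. In Dox against Vehicle estrogen-induced genes had 15 higher, amino acid stress genes 5 lower and oxidative phosphorylation genes 7 higher. Lists not called in E2 against Vehicle had the following adjusted p: pathway components 0.602, jointly controlled genes 0.402, luminal genes 0.441, basal and stem-like markers 0.806, mesenchymal genes 0.619, matrix genes 0.966, interferon response 0.467, antigen presentation 0.112, acute phase genes 0.465 and TNF receptors 0.334. It was 0.551 for apoptosis regulators, 0.913 for growth factor genes, 0.0831 for p53 targets, 0.0691 for amino acid stress genes, 0.178 for unfolded protein response genes, 0.42 for glycolysis and hypoxia genes, 0.698 for fibroblast markers, 0.724 for blood cell markers, 0.862 for endothelial markers and 0.507 for housekeeping genes. Lists not called in Dox against Vehicle were the jointly controlled genes (adjusted p = 0.617), basal and stem-like markers (0.967), mesenchymal genes (0.275), TGF-β and BMP targets (0.275), apoptosis regulators (0.255), growth factor genes (0.282), p53 targets (0.367), glycolysis and hypoxia genes (0.805) and oxidative phosphorylation genes (0.367). The same held for fibroblast markers (0.805), endothelial markers (0.78) and housekeeping genes (0.967). Among these uncalled lists the median, mean and test direction differed in sign for basal, growth factor, glycolysis, fibroblast, mesenchymal, endothelial, growth arrest, estrogen-induced or housekeeping genes in E2 or Dox, and their members went both ways.

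With both treatments the cells showed the NF-κB program of Dox and the estrogen program of E2 side by side, and most DNA replication and mitotic genes lay above Vehicle. This comparison asks what E2 and Dox together changed. NF-κB targets had 27 of 31 higher and 3 lower (median 1.28, adjusted p = 1.78e-07, and adjusted p = 0.0243 with an estimated correlation), with CCL2 up by at least 5.63 and TNFAIP3 at 4.88 ± 0.08. Estrogen-induced genes had 31 of 34 higher (median 1.42, adjusted p = 3.92e-13, and adjusted p = 0.0243 with an estimated correlation), with EGR3 at 4.48 ± 0.09, PGR at 3.99 ± 0.09 and GREB1 at 2.76 ± 0.11. Acute phase genes had 11 of 12 higher (median 2.86, adjusted p = 7.74e-07, and adjusted p = 0.038 with an estimated correlation), with S100A9 up by at least 7.65 and the protease inhibitor SERPINA3 at 5.75 ± 0.12. Their median ranged from 0.41 to 5.75 with the filter, and the call held.

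**Figure D3:**
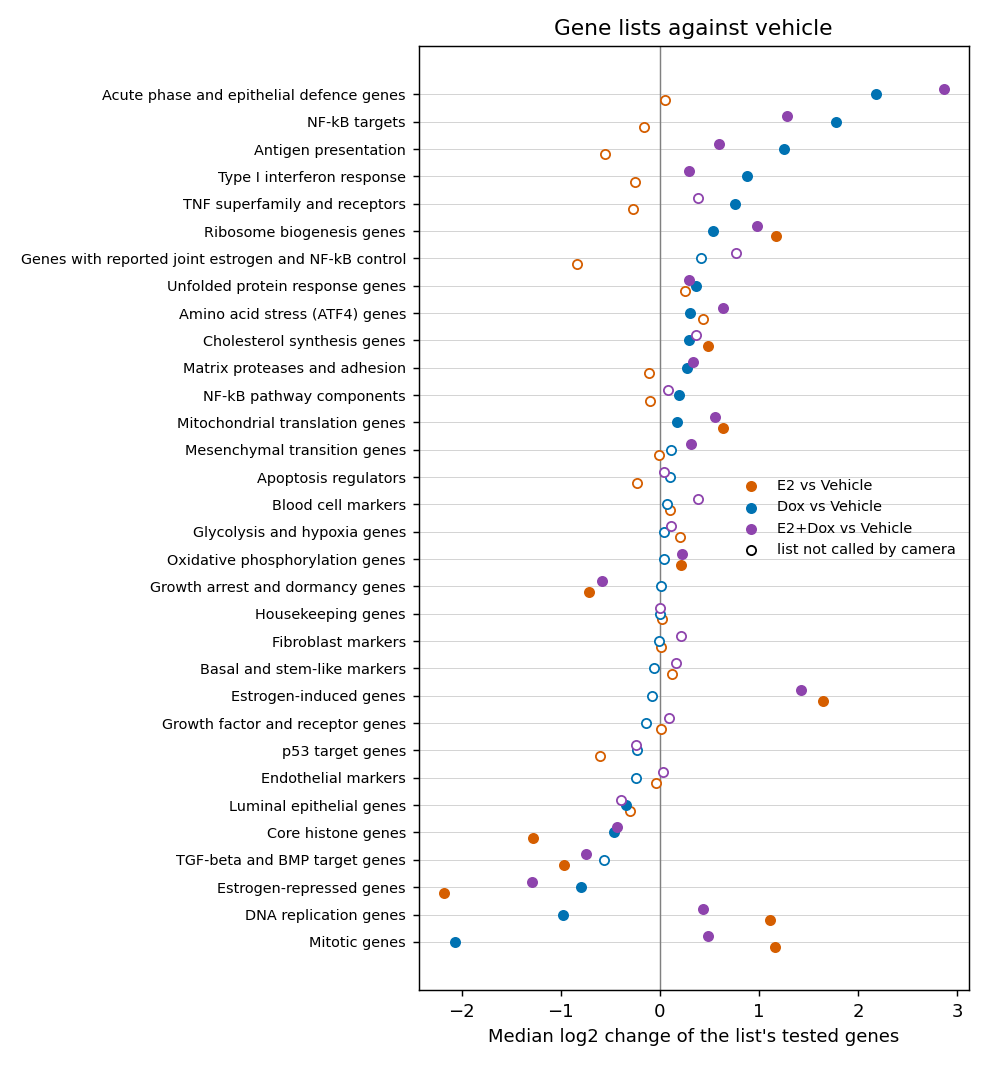
Median log2 change of the tested genes of each gene list against Vehicle, for E2, Dox and E2+Dox; filled points are lists called by camera at an adjusted p of 0.05 and open points are not. Mitotic genes had medians of 1.16 with E2, -2.07 with Dox and 0.48 with both, and NF-κB targets -0.16, 1.78 and 1.28.

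Mitotic genes had 28 of 34 higher than Vehicle and 1 lower, with a median of 0.48 (adjusted p = 2.58e-05, and adjusted p = 0.332 with an estimated correlation). DNA replication genes had 29 of 34 higher, with a median of 0.43 (adjusted p = 3.73e-06, and adjusted p = 0.134 with an estimated correlation). CDC20 rose by 1.29 ± 0.08 and MCM10 by 1.03 ± 0.07. MKI67 stood at 0.27 (adjusted p = 0.0115) at its brightest probe set. That call was lost without E2+Dox replicate 1 or Vehicle replicate 1 (0.22 and 0.21) and at the mean of its probe sets (-0.0033). CDKN1A did not pass (-0.02, adjusted p = 0.752), and its sign was positive without Vehicle replicate 1 (0.014) or E2+Dox replicate 3 (0.037). IKBKB rose by 2.26 ± 0.12, ESR1 fell (-1.98 ± 0.06), and among the jointly controlled genes PHLDA1 (1.16 ± 0.11) and PTGES (0.77 ± 0.10) rose and ABCG2 fell (-1.24 ± 0.06). Ribosome biogenesis genes had 24 of 24 higher (median 0.98, adjusted p = 1.98e-10, and adjusted p = 0.104 with an estimated correlation). Mitochondrial translation genes had 21 of 22 higher (median 0.56, adjusted p = 7.74e-07, and adjusted p = 0.122 with an estimated correlation). Amino acid stress genes had 14 of 21 higher (median 0.64, adjusted p = 0.000805, and adjusted p = 0.122 with an estimated correlation), with SLC7A11 at 3.61 ± 0.11. Antigen presentation genes had 11 of 14 higher (median 0.59, adjusted p = 0.0028, and adjusted p = 0.111 with an estimated correlation). Estrogen-repressed genes had 9 of 11 lower (median -1.29, adjusted p = 0.000805, and adjusted p = 0.122 with an estimated correlation). Core histone genes had 9 of 13 lower (median -0.44, adjusted p = 0.0207, and adjusted p = 0.161 with an estimated correlation). Oxidative phosphorylation genes had 20 of 28 higher (median 0.22, adjusted p = 0.00471, and adjusted p = 0.307 with an estimated correlation).

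Mesenchymal genes had 8 of 11 higher (median 0.31, adjusted p = 0.023, and adjusted p = 0.122 with an estimated correlation), with the matrix protein FN1 at 1.91 ± 0.08. That call was lost without a filter on dim probe sets (median 0.17, adjusted p = 0.0653), with quantile normalization (0.25, adjusted p = 0.05) and with the ACTB covariate (0.24, adjusted p = 0.0621). Blood cell markers had 4 of 4 higher (median 0.38, adjusted p = 0.0548, so not called) and fibroblast markers 2 of 3. In the same comparison the background of GC-rich control probe sets was higher by 0.23 in E2+Dox, and the median change over all genes with a mean signal between 5 and 6 was 0.16. Other large changes were those of AKR1C1 (at least 5.50), the epithelial transcription factor EHF (at least 4.77) and AKR1C3 (at least 4.88), which rose, and IL1R1 (-5.78 or lower), ACKR3 (-4.78 ± 0.12) and the Wnt ligand WNT11 (-3.84 ± 0.13), which fell. AKR1C1 and AKR1C3 belong to a family with much shared sequence.

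In limma 8739 genes (70%) changed, 4370 higher and 4369 lower, and 507 and 613 of them by at least 2-fold, while 9125 genes (73.1%, against 10% by chance) did not overlap between the groups. The share of higher genes, 50%, was 34.4% after the housekeeping shift, which moved the median of all genes to -0.1. Adjusted over the list alone, DNA replication genes had 30 higher and glycolysis and hypoxia genes 12 higher, and the other lists gave the counts found over all genes. A further group of calls lay at the threshold and was lost when single arrays were left out. For interferon response (adjusted p = 0.0475) these were each Dox array, E2 replicate 1, E2+Dox replicate 2 or 3 and Vehicle replicate 2 or 3 (up to 0.15). The same happened to unfolded protein response genes (0.0475) without Dox replicate 1, E2 replicate 1, E2+Dox replicate 3 or Vehicle replicate 2 or 3 (up to 0.0569), and to growth arrest genes (0.0475) without Dox replicate 1, E2 replicate 1, E2+Dox replicate 3 or Vehicle replicate 2 (up to 0.0577). It happened to matrix genes (0.0475) without Dox replicate 1, E2+Dox replicate 3 or Vehicle replicate 2 (up to 0.0577) and TGF-β and BMP targets (0.039) without Dox replicate 1 (0.0506). With an estimated correlation their adjusted p = 0.168, 0.134, 0.279, 0.168 and 0.161. Between the alternatives the values of EGR3 (1.34 to 4.66), PGR (2.33 to 4.24), GREB1 (1.76 to 2.95), IKBKB (1.30 to 2.48), ESR1 (-2.11 to -0.94) and PHLDA1 (0.98 to 1.80) moved by over 1.5 times. So did PTGES (0.64 to 3.01), FN1 (1.09 to 2.13), EHF (2.50 to 6.30), AKR1C3 (2.49 to 5.05) and IL1R1 (-6.48 to -3.28). Medians did for NF-κB targets (0.43 with no filter, up to 1.53), estrogen-repressed (-1.68 to -0.64), core histone (-0.71 to -0.28), mesenchymal (0.17 to 0.49) and oxidative phosphorylation genes (0.094 to 0.31).

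In the presence of estrogen, Dox again raised NF-κB targets, acute phase genes, antigen presentation and interferon response genes, and lowered DNA replication and mitotic genes, the mitotic genes by less than it did alone. E2+Dox against E2 asks what Dox changed in estrogen-treated cells. NF-κB targets had 25 of 31 higher (median 1.43, adjusted p = 5.08e-18, and adjusted p = 0.00232 with an estimated correlation), with CCL2 up by at least 5.63, TNFAIP3 up by at least 5.04, NFKBIA at 2.12 ± 0.05 and CXCL8 up by at least 2.30. Acute phase genes had 9 of 12 higher (median 2.80, adjusted p = 4.35e-09, and adjusted p = 0.0143 with an estimated correlation), with S100A9 up by at least 7.66 and C3 up by at least 5.04, and here the median ranged from 0.30 to 4.59 with the filter. Antigen presentation genes had 11 of 14 higher (median 0.94, adjusted p = 6.21e-08, and adjusted p = 0.0143 with an estimated correlation). Interferon response genes had 12 of 17 higher (median 0.43, adjusted p = 4.99e-05, and adjusted p = 0.0289 with an estimated correlation). IKBKB rose by 2.32 ± 0.12 (adjusted p = 4.84e-09).

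Each of the 34 mitotic genes fell (median -0.78, adjusted p = 1.14e-18, and adjusted p = 0.0714 with an estimated correlation), with CCNA2 at -1.01 ± 0.10 and MKI67 at -0.68 ± 0.08. So did 33 of 34 DNA replication genes (median -0.77, adjusted p = 1.68e-20, and adjusted p = 0.0143 with an estimated correlation), with E2F8 at -1.25 ± 0.11. CDKN1A rose by 2.13 ± 0.06. Of 34 estrogen-induced genes 25 fell and 3 rose (median -0.37, adjusted p = 6.21e-08, and adjusted p = 0.0373 with an estimated correlation), with SUSD3 at -1.57 ± 0.05 and PGR at -0.51 ± 0.09, while TFF1 did not pass (-0.06, adjusted p = 0.398). With signals of 14.41 in E2 and 14.35 in E2+Dox, where the highest signal of an array was as low as 14.76, TFF1 is too close to saturation to show a lack of change. GREB1 stood at -0.30 (adjusted p = 0.0319), a call lost without E2 replicate 1 or 2 or E2+Dox replicate 2 or 3, at -0.33, -0.17, -0.28 and -0.29. Estrogen-repressed genes had 10 of 11 higher (median 0.55, adjusted p = 8.22e-06, and adjusted p = 0.0386 with an estimated correlation), with PIK3IP1 at 2.29 ± 0.07 and TP53INP1 at 2.07 ± 0.07. Amino acid stress genes had 17 of 21 higher (median 0.40, adjusted p = 8.22e-06, and adjusted p = 0.0381 with an estimated correlation), with DDIT4 at 1.98 ± 0.08. Matrix genes had 11 of 17 higher (median 0.38, adjusted p = 0.00044, and adjusted p = 0.0386 with an estimated correlation), with the integrin ITGAV at 1.74 ± 0.10. TNF receptors had 6 of 8 higher (adjusted p = 0.000187, and adjusted p = 0.0658 with an estimated correlation). Apoptosis regulators had 9 of 16 higher (adjusted p = 0.00139, and adjusted p = 0.0674 with an estimated correlation), including the death-promoting genes BBC3 (1.49 ± 0.09) and BCL2L11 (1.02 ± 0.06). The transcription factor SOX9 rose by 3.63 ± 0.09, and ESR1 fell further below its level with E2 alone (-0.94 ± 0.06).

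E2+Dox and E2 differed in 5742 genes (46%) in limma, 2954 higher and 2788 lower, of which 303 and 102 by at least 2-fold, and 7441 genes (59.6%, against 10% by chance) did not overlap. Adjusted over the list alone, higher genes numbered 26 for NF-κB targets, 12 for matrix genes, 13 for interferon response genes, 10 for apoptosis regulators, 6 for pathway components and 10 for p53 targets. Glycolysis and hypoxia genes then had 14 lower, growth arrest genes 4 lower, basal markers 2 lower, and oxidative phosphorylation genes 1 higher and 2 lower, and the other lists were unaffected. The share of higher genes, 51.4%, was 74.1% after the housekeeping shift, which moved the median of all genes to 0.13, and 36.9% after a shift to the same array median. Calls that did not hold with an estimated correlation were also made for pathway components, luminal genes, p53 targets, glycolysis and hypoxia genes, ribosome biogenesis genes and core histone genes (adjusted p = 0.03, 0.0227, 0.03, 0.018, 0.00387 and 0.0247; adjusted p = 0.0843, 0.206, 0.189, 0.15, 0.245 and 0.15 with an estimated correlation). The alternatives moved CXCL8 (1.51 to 2.80), IKBKB (1.54 to 2.43), PGR (-0.80 to -0.28), GREB1 (-0.51 to -0.14), PIK3IP1 (1.01 to 2.40), TP53INP1 (1.07 to 2.18), BCL2L11 (0.42 to 1.12) and ESR1 (-1.01 to -0.40) by over 1.5 times. They moved as much the medians of antigen presentation (0.49 to 1.63), interferon response (0.26 to 0.54), estrogen-repressed (0.31 to 0.70) and matrix genes (0.26 to 0.61).

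Estrogen still acted on its targets in Dox-treated cells and lifted mitotic and DNA replication genes far above their level with Dox alone. E2+Dox against Dox asks what estrogen changed in the presence of Dox. Each of the 34 estrogen-induced genes rose (median 1.21, adjusted p = 5.2e-21, and adjusted p = 0.00933 with an estimated correlation), with PGR at 4.63 ± 0.09, GREB1 at 4.55 ± 0.11 and the MYB relative MYBL1 at 4.50 ± 0.14. Each of the 34 mitotic genes rose (median 2.40, adjusted p = 3.62e-29, and adjusted p = 0.0677 with an estimated correlation), with NDC80 at 3.04 ± 0.10 and MKI67 at 2.44 ± 0.08. So did 33 of 34 DNA replication genes (median 1.31, adjusted p = 1.28e-22, and adjusted p = 0.022 with an estimated correlation), with MCM10 at 2.81 ± 0.07 and RRM2 at 2.73 ± 0.05. CDKN1A fell (-1.40 ± 0.06).

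IKBKB was lower in E2+Dox than in Dox, with a change of -1.49 ± 0.12 (adjusted p = 2.65e-07), and across its 8 Dox-raised probe sets the difference was -1.89 to -1.15. NF-κB targets had 21 of 31 lower and 2 higher (median -0.35, adjusted p = 0.000146, and adjusted p = 0.0677 with an estimated correlation), with the adhesion molecule ICAM1 at -1.80 ± 0.07, IL32 at -1.71 ± 0.11, NFKBIA at -0.48 ± 0.05 and TNFAIP3 at -0.58 ± 0.08. CXCL8 did not pass (-0.30, adjusted p = 0.0821), although it did without E2+Dox replicate 2 (-0.40) and without Vehicle replicate 1 or 3. Antigen presentation genes had 10 of 14 lower (median -0.69, adjusted p = 0.00101, and adjusted p = 0.0677 with an estimated correlation), with HLA-B at -1.66 ± 0.14. Interferon response genes had 10 of 17 lower (median -0.62, adjusted p = 0.0154, and adjusted p = 0.13 with an estimated correlation), with IRF9 at -1.43 ± 0.07. Acute phase genes went both ways and were not called (adjusted p = 0.53): the serum amyloid gene SAA1 (at least 0.32) and SLPI (1.59 ± 0.07) rose and CFB fell (-1.46 ± 0.11). TNF receptors had 6 of 8 lower (adjusted p = 0.00465, and adjusted p = 0.167 with an estimated correlation). TGF-β and BMP targets had 11 of 13 lower (adjusted p = 0.0029, and adjusted p = 0.0976 with an estimated correlation). Ribosome biogenesis genes had 22 of 24 higher (median 0.46, adjusted p = 9.7e-08, and adjusted p = 0.113 with an estimated correlation). The apoptosis inhibitor BCL2 rose by 1.89 ± 0.08, VIM by at least 0.40, CD44 by 1.53 ± 0.05 and IGFBP5 by 3.77 ± 0.08. ESR1 rose by 0.38 ± 0.06, and PHLDA1 fell (-1.27 ± 0.11).

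Estrogen changed 7286 genes (58.4%) in Dox-treated cells in limma, 3391 higher and 3895 lower, of which 407 and 200 by at least 2-fold, with 7899 genes (63.3%, against 10% by chance) that did not overlap. Higher genes made up 46.5%, and 40.1% and 39.1% after the shifts to the same housekeeping mean and the same array median. Adjusted over the list alone, NF-κB targets had 3 higher, pathway components 10 lower, basal markers 6, matrix genes 3, mesenchymal genes 8 and glycolysis genes 8 higher. Amino acid stress genes had 12 higher, oxidative phosphorylation genes 17 higher and fibroblast markers 2 higher, no endothelial marker was lower, and the other lists were unaffected. Calls were also made for pathway components, growth arrest genes, oxidative phosphorylation genes and mitochondrial translation genes (adjusted p = 0.0214, 0.0214, 0.00334 and 3.76e-05; adjusted p = 0.106, 0.233, 0.31 and 0.181 with an estimated correlation). Changes by over 1.5 times between the alternatives were seen in PGR (2.57 to 4.84), GREB1 (2.54 to 4.70), CXCL8 (-0.40 to -0.017), BCL2 (0.98 to 2.08), IGFBP5 (2.30 to 3.96), ESR1 (0.23 to 0.44) and the median of interferon response genes (-0.66 to -0.13).

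**Figure D4:**
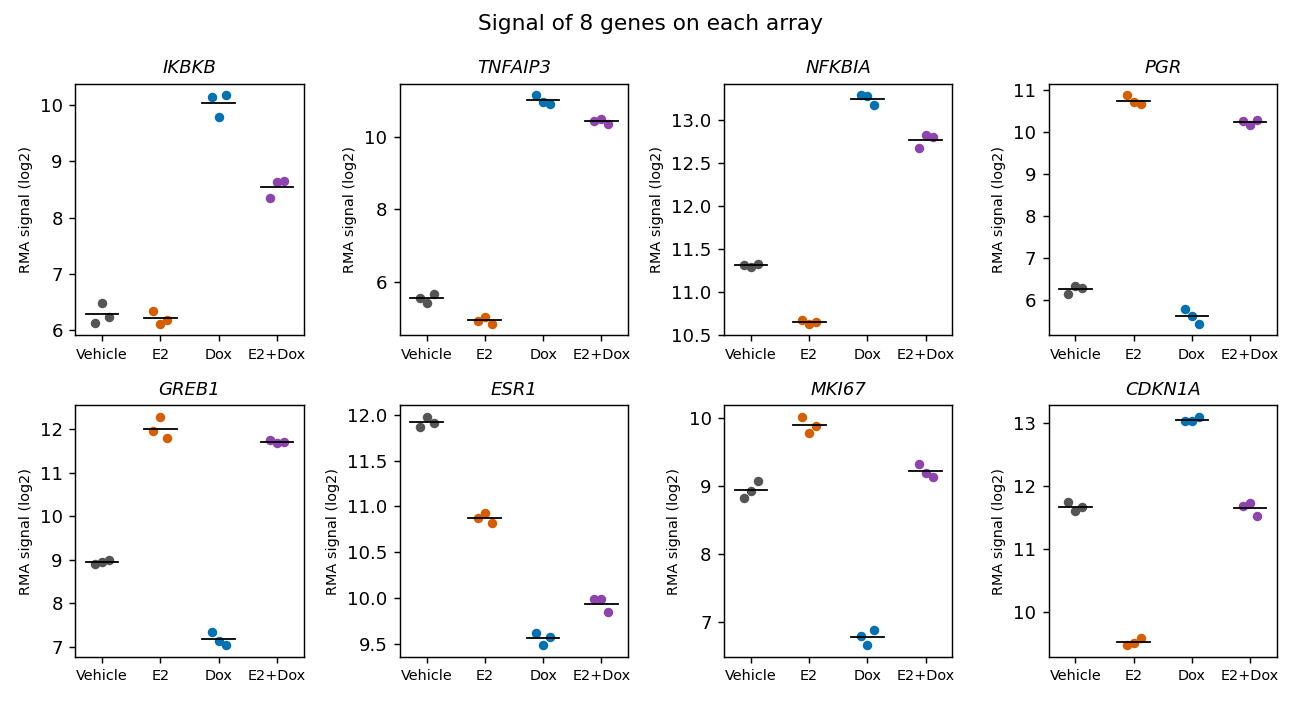
RMA signal (log2) of 8 genes on each of the 12 arrays, by group; points are arrays and lines are group means. IKBKB lay at 10.03 ± 0.22 (SD, n = 3) in Dox and 8.54 ± 0.17 in E2+Dox, and MKI67 at 6.78 ± 0.11 and 9.21 ± 0.09.

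The effects of E2 and Dox did not add up: many genes that both moved the same way changed by less than the sum of the separate effects, and mitotic genes fell far less with Dox when estrogen was present. The interaction, the effect of Dox with E2 minus its effect without, asks whether the combination differs from that sum on the log2 scale. Mitotic genes had 30 of 34 with a positive interaction (median 1.33, adjusted p = 8.86e-14, and adjusted p = 0.281 with an estimated correlation), such as TOP2A (2.15 ± 0.09), NDC80 (1.96 ± 0.14) and MKI67 (1.49 ± 0.12). NF-κB targets showed no shift called as a list (7 positive and 10 negative of 31, median -0.0703, adjusted p = 0.334). The interaction did not pass in TNFAIP3 (0.03, adjusted p = 0.834) or CXCL8 (-0.07, adjusted p = 0.8), nor in NFKBIA (0.18, adjusted p = 0.0737), which passed without E2+Dox replicate 1 (0.22). It was negative in IL32 (-1.71 ± 0.15), PLAU (-1.45 ± 0.21) and IKBKB (-1.43 ± 0.17).

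**Figure D5:**
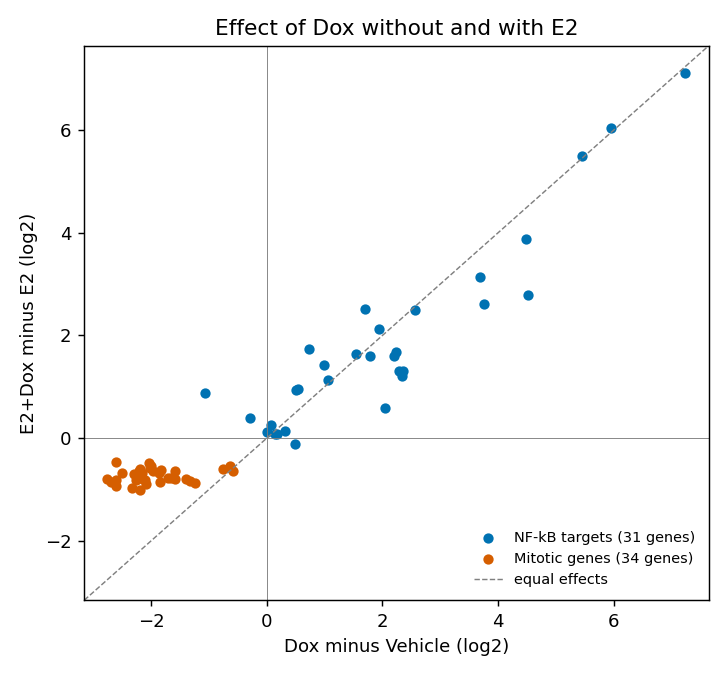
Log2 change with Dox without E2 (horizontal) and with E2 (vertical) for 31 NF-κB targets and 34 mitotic genes; each point is a gene and the dashed line marks equal effects. Mitotic genes fell by a median of 2.07 without E2 and 0.78 with it, whereas the medians of NF-κB targets were 1.78 and 1.43.

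Estrogen-repressed genes had 10 of 11 with a positive interaction (median 1.85, adjusted p = 8.25e-06, and adjusted p = 0.115 with an estimated correlation), led by BLNK (4.63 ± 0.10) and PIK3IP1 (2.92 ± 0.11). So did core histone genes, with 12 of 13 (median 0.87, adjusted p = 2.42e-05, and adjusted p = 0.115 with an estimated correlation). Ribosome biogenesis genes had 22 of 24 with a negative interaction (median -0.72, adjusted p = 5.23e-10, and adjusted p = 0.115 with an estimated correlation), such as NOP16 (-1.63 ± 0.08). Negative medians were also called for mitochondrial translation (-0.32), cholesterol synthesis (-0.42), unfolded protein response (-0.42) and estrogen-induced genes (-0.36), with adjusted p = 0.000174, 0.00475, 0.0115 and 0.00251 (adjusted p = 0.281, 0.281, 0.115 and 0.281 with an estimated correlation). The calls for p53 targets (median 0.70, adjusted p = 0.0189, and adjusted p = 0.281 with an estimated correlation) and DNA replication genes (median 0.28, adjusted p = 0.0381, and adjusted p = 0.43 with an estimated correlation) were lost without Vehicle replicate 1 (adjusted p = 0.0513) and Vehicle replicate 3 (0.0672), respectively. ESR1 had a positive interaction of 1.42 ± 0.08, being lowered by each treatment (-1.04 and -2.36) and by both (-1.98), and GREB1 of 1.48 ± 0.15, having been lowered by Dox alone. For GREB1 this holds for the brightest probe set: the other 2 had interactions of -0.49 and -0.21 without a fall with Dox that passed, and the mean of the 3 gave 0.26 (adjusted p = 0.0418). The largest interactions were those of BLNK, IL1R1 (4.13 ± 0.22) and SOX9 (3.90 ± 0.13) on the positive side and of ARMCX3 (-3.40 ± 0.15), the phosphatase DUSP5 (-3.05 ± 0.14) and the neuropeptide gene GAL (-2.94 ± 0.10) on the negative. Interactions of IL1R1, ARMCX3, PLAU, TNFAIP3, CXCL8 and VIM rest on groups under the 40th percentile, so their sizes are not known. Interactions of PGR, PTGES, PHLDA1 and CD44 differed in sign between ways of choosing a probe set. That of VIM (0.35, adjusted p = 0.049) was lost when any single array except Dox replicate 2 was left out, with adjusted p from 0.0514 without E2 replicate 3 to 0.117 without Dox replicate 1.

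The interaction passed in limma in 6272 genes (50.2%), 3397 positive and 2875 negative, of which 596 and 315 by at least 2-fold. The share of positive interactions, 54.2%, was 78.1% after the housekeeping shift, which moved the median of all genes to 0.24, and 41.8% after the shift to the same array median. Adjusted over the list alone, mitotic genes had 31 positive, DNA replication genes 7 negative and unfolded protein response genes 11 negative, and the other called lists gave the same counts. Among the lists not called in the 4 comparisons with E2+Dox, the median, mean and test direction differed in sign for growth factor, glycolysis, endothelial, cholesterol synthesis and blood cell genes in some of these. Between the alternatives, interactions moved by over 1.5 times in MKI67 (0.99 to 1.71), IKBKB (-1.60 to -0.90), PIK3IP1 (1.35 to 3.12), ESR1 (0.77 to 1.62), GREB1 (0.26 to 1.68), NFKBIA (0.083 to 0.37) and IL1R1 (2.29 to 4.44). Medians did in mitochondrial translation (-0.41 to -0.12), cholesterol synthesis (-0.52 to -0.23), unfolded protein response (-0.57 to -0.22), estrogen-induced (-0.45 to -0.16) and DNA replication genes (0.17 to 0.48).

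E2 and Dox both raised 1940 genes and both lowered 2430, while 791 were raised by E2 and lowered by Dox and 824 the reverse. Independent calls would share 1117 and 1410, but both comparisons use the same Vehicle arrays, so this is no fair measure of a common response. Dox without and with E2, which share no array, both raised 1384 genes and both lowered 1494, where 842.7 and 866.6 would be shared by independent calls. Another 587 genes were raised by Dox without E2 and lowered by it with E2, and 691 the reverse. Independent calls would give 795.4 and 918.2 of these. Among genes with an interaction, 1665 of the 1679 raised by both (99.2%) and 2075 of the 2079 lowered by both (99.8%) changed by less than the sum. In E2+Dox 564 genes lay above both single treatments and 490 below both. Independent calls would give 802.5 and 870, without allowance for the shared E2+Dox arrays. Arrays simulated without effects gave 0 genes in every such pattern, which follows from the lack of calls and measures no joint effect. The largest of the former, by the smaller of the differences, were GLYATL2, AKR1C2, AKR1C1 and the glucocorticoid-induced kinase SGK1. Above the nearer single treatment, GLYATL2 lay by at least 2.02, a bound, and AKR1C2, AKR1C1 and SGK1 by measured differences of 2.28, 2.08 and 1.77. The largest of the latter were EIF5A2, B3GNT5 and HOXB7, at -0.86, -0.80 and -0.74. Between the alternatives EIF5A2 ran from -0.973 to -0.558 and B3GNT5 from -0.951 to -0.445 against E2, so their order is not fixed. GLYATL2, AKR1C2, SGK1, EIF5A2, B3GNT5 and HOXB7 were named after their values were seen.

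Across the 12482 genes, which are not independent replicates, the changes with E2 and with Dox alone had a Pearson correlation of 0.308, and 0.496 would arise from the shared Vehicle arrays alone in simulated data without effects. Their covariance was 0.141, against 0.00305 simulated. The effect of Dox without E2 and its effect with E2, which share no array, correlated with r = 0.55 (Spearman 0.303), and the effect of E2 without Dox and with Dox with r = 0.625 (Spearman 0.616). The counts above and below both single treatments depended on scaling and filters, since they became 301 and 890 after the shift to the same array median and 24 and 0 when a change of at least 2-fold was required of both differences.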

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

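Of the tests in this part, those of the cell's own IKBKB transcript, of signals of matched brightness and of a single scaling of all Dox effects were chosen after the result had been seen. The test of the interaction flagged 6272 genes whose response to Dox differed between cells with and without E2. Of 100 groupings of the residuals of a fit without interaction, 1, the real one, gave as many, with 0 genes at most in the others. Those residuals still hold the interaction, which widens the spread in every other grouping, so this cannot decide on chance. It is also not known whether the samples of a group were separate cultures. In each of the 5 differences between groups the real grouping was 1 of only 10 possible, too few for a share under 0.05: it gave 8450, 7441, 8739, 5742 and 7286 genes (E2, Dox and E2+Dox against Vehicle, then E2+Dox against E2 and against Dox), and the others at most 0. For gene lists called, the real and highest other numbers in the same order were 11 and 9, 17 and 14, 18 and 13, 18 and 15, and 13 and 11. Every other grouping in these differences mixes arrays of both groups unevenly. It keeps part of their difference and widens the spread, so neither the gene nor the list numbers are levels expected by chance. For the interaction 3 of 100 such groupings of residuals gave as many lists, with 10 in the real one and at most 10 in the others. Other groupings thus reached the same number, and 0 of the 10 lists were called with an estimated correlation, so chance is not excluded. For genes beyond both single treatments, 3 of 100 groupings gave as many above (564, at most 1383 in the others) and 3 of 100 as many below (490, at most 1651). That does not exclude chance, because regrouping mixes arrays that truly differ and the count was as large only where a true group stood whole as the combined one. The other large counts, 1383 and 1356 above and 1642 and 1651 below, came from groupings in which the 3 E2 arrays stood as the combined group and Dox and E2+Dox arrays were mixed.

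The response to Dox differed with E2 in 10 gene lists, by median interactions of -0.36 for estrogen-induced, 1.85 for estrogen-repressed, 0.28 for DNA replication, 1.33 for mitotic, 0.70 for p53 target, -0.42 for unfolded protein response, -0.42 for cholesterol synthesis, -0.32 for mitochondrial translation, -0.72 for ribosome biogenesis and 0.87 for core histone genes, none of which was called with an estimated correlation. Among single genes it differed most in BLNK (4.63), IL1R1 (4.13), SOX9 (3.90), HMCN1 (3.76), CSTA (3.57), KLHL24 (3.37), ARHGEF37 (3.295), SELENOP (3.29), TXNIP (3.27) and SASH1 (3.22) on the positive side. On the negative side these were ARMCX3 (-3.40), DUSP5 (-3.05), GAL (-2.94), ETV5 (-2.80), HEY2 (-2.74), FJX1 (-2.73), PDLIM3 (-2.69), ELOVL2 (-2.48), FRK (-2.48) and CYP4F11 (-2.45). Sizes are not known for IL1R1, HMCN1, CSTA, ARMCX3, PDLIM3 and FRK, each with a group under the 40th percentile of its arrays. The response to Dox also differed in IKBKB (-1.43), ESR1 (1.42), GREB1 (1.48) and MKI67 (1.49). Between the alternatives the interactions of ARHGEF37 (1.29 to 3.49) and SASH1 (1.77 to 3.42) moved by over 1.5 times too. The background of GC-rich control probe sets, which no comparison uses, was higher by 0.235 in E2+Dox than in Vehicle (exact two-sided permutation p = 0.1, the smallest possible). Of 2461 bright probe sets without a single symbol, 1577 changed with E2, 1339 with Dox and 1590 with both, against Vehicle. Groups of 3 are too small for the rule on single outlying samples.

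The IKBKB probe sets raised by Dox lay lower in E2+Dox than in Dox by 1.15 to 1.89 log2 units. Compression of signals of this brightness is argued against by 2775 genes as bright in Dox and not raised by it, whose median change was -0.0632 (quartiles -0.27 and 0.18). If the 3 probe sets that Dox does not raise read the cell's own transcript, which the files do not say, a fall of that transcript is argued against by their largest fall of -0.281 here, although they stood at -0.72 to -0.16 with E2 alone. Without that assumption, loss of the whole signal present in Vehicle could change the raised probe sets by at most -0.32, and only a transcript that Dox itself raised stays open. Compression of strongly raised signals stays open, since 81 other genes raised as much had a median change of -0.881 (quartiles -1.4 and -0.47), and those genes may also be lower because they follow the kinase, while a lower yield of the Dox-raised IKBKB transcript in the presence of E2 is a biological candidate that these arrays do not test.

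Mitotic genes fell less with Dox when E2 was present. A higher background on the E2+Dox arrays is argued against by the median interaction of 1.42 with that background as a covariate (camera adjusted p = 2.76e-14). The slope through 0 of the Dox change with E2 on that without it was 0.877 (SE 0.045) for NF-κB targets. It was 0.354 (SE 0.018) for mitotic genes. These SEs are taken across genes that share the same arrays, so they do not measure the spread between samples. Such a slope gives most weight to the largest changes, such as CCL2 (7.24 without E2), measured against a group under the 40th percentile. The median Dox change was 1.78 without and 1.43 with E2 for NF-κB targets, and -2.07 and -0.776 for mitotic genes. These medians argue against a single scaling of all Dox effects by the lower IKBKB level, but their difference between lists was not tested across samples. A response that depends on the IKBKB level in a nonlinear way stays open. A drive by E2 of equal log2 size with and without Dox cancels in these changes and could not give these slopes. The median E2 change of mitotic genes was 1.16 without Dox and 2.40 with Dox, which argues against such an equal drive. A drive by E2 that is larger in the presence of Dox stays open.

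Changes made the same way by E2 and Dox combined to less than their sum in 3740 of 4370 genes. Noise of the shared Vehicle arrays gave 0 such calls on average in 20 simulations without interaction, among 2340 genes changed the same way by both on average. That follows from the lack of any interaction in the simulations, so it does not measure how far such noise bends the pattern. The floor of the array is argued against by 84.2% of the 1649 lowered genes with an expected level above 7. The ceiling is argued against by 78% of the 902 raised genes with an expected level under 10. With the ACTB difference as a covariate 93.8% of the 3740 genes were still called. That difference itself separates E2 and E2+Dox from Vehicle, so the covariate cannot decide on RNA integrity, which stays open. Another offset shared by the 3 Vehicle arrays stays open, because component 2 separates Vehicle from the other groups, and it may account for part of the pattern. A common program that either treatment can fill is a biological candidate, and 1003 of these genes (26.8%) did not differ by the threshold between E2+Dox and either single treatment.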

How the results depend on the processing

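The ACTB covariate, the GC-rich background covariate and the mean level of at least 7 were chosen after the results had been seen, and all other alternatives before. Of 307 single-gene results, 7789 values under alternatives kept direction and side of the threshold, 47 lost it, 27 gained it and 34 changed sign. The counts of changed genes stayed within 1.5 times except at 2-fold, where the added condition left 1555 (E2), 1083 (Dox), 1120 (E2+Dox against Vehicle), 405 (against E2), 607 (against Dox) and 911 (interaction). Without single arrays they ranged from 7924 to 8608, 6855 to 7404, 8094 to 8900, 4902 to 5973, 6419 to 7468 and 5808 to 6377. With a replicate block they were 8347, 7294, 8641, 5520, 7118 and 6071. With an estimated correlation the lists called numbered 1, 6, 3, 9, 2 and 0 in this order, and the cause was not tested. With fry, which asks whether a list moves and not whether it differs from other genes, they numbered 28, 26, 29, 30, 30 and 27, and with the mean of a gene's probe sets the interaction had 16. Without single arrays they ranged from 11 to 12, 16 to 17, 13 (without Dox replicate 1) to 20 (without E2+Dox replicate 1), 18 to 19, 13 to 15 and 9 to 12. Dim signals near the background limit what can be tested, and 68.8% of genes passed the filter.

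Genes above and below both single treatments numbered 267 and 238 at an adjusted p of 0.01 and 24 and 0 at 2-fold. They numbered 301 and 890 with arrays shifted to the same median, 895 and 766 with array weights, 249 below with the housekeeping shift and 369 above with the GC-rich background covariate, and the cause was not tested. Without single arrays they ranged from 417 to 624 and from 349 to 537, lowest without E2+Dox replicate 1 and highest without Dox replicate 3. The correlations of E2 with Dox, of Dox without and with E2 and of E2 without and with Dox were 0.39, 0.303 and 0.616 by Spearman, 0.314, 0.54 and 0.616 with no filter, 0.296, 0.56 and 0.634 at the 60th percentile, and 0.3002 to 0.313, 0.542 to 0.556 and 0.62 to 0.636 without single arrays.

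Signs changed as follows, and the cause was not tested. Among list medians, pathway components were at -0.014 with Dox and -0.020 against E2 with the most variable probe set, oxidative phosphorylation with E2 at -0.011 with the housekeeping shift and interferon response in E2+Dox against Vehicle at -0.0019 at a mean level of at least 7. Among single genes, with the mean of a gene's probe sets, MKI67 in E2+Dox against Vehicle was at -0.0033, and the interactions of PGR, TNFAIP3, PTGES, PHLDA1 and CD44 were at -0.55, -0.15, -0.39, -0.24 and -0.23. With the most variable probe set those of PTGES, PHLDA1 and CD44 were at -1.19, -0.077 and -0.47. With arrays shifted to the same median those of TNFAIP3 and PTGES were at -0.0598 and -0.034. With the housekeeping shift TFF1 against E2 was at 0.044 and the CXCL8 interaction at 0.13, and the latter at 0.017 with array weights. With the ACTB covariate E2 against Vehicle was at 0.22 in IKBKB and 0.085 in CXCL8, and the interactions of PGR and TNFAIP3 were at -0.059 and -0.045. With the GC-rich background covariate TFF1 against E2 was at 0.00011 and the interactions of CXCL8 and PTGES at 0.21 and -0.00031. Without single arrays CDKN1A in E2+Dox against Vehicle ranged from -0.064 to 0.037, IKBKB in E2 against Vehicle from -0.14 to 0.033, and the interactions of CXCL8 from -0.21 to 0.074, PTGES from -0.045 to 0.16 and TNFAIP3 from -0.022 to 0.105. Those of CXCL8, TNFAIP3 and TFF1 are measured signals near the floor or the top of the arrays. The alternative foreseen for linear values was not run, since the deposited values are already log2.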

Other observations

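Of the tests in this part, that of a weaker NF-κB response was chosen after the result had been seen, and those of NRF2 targets before it. AKR1C1, AKR1C2 and AKR1C3, enzymes that reduce steroids and other carbonyls, rose with Dox and rose again with E2 on top of Dox. AKR1C1 (Entrez gene 1645) had a log2 signal of 3.77 ± 0.03 (SD, n = 3) in Vehicle, 5.06 ± 0.32 in E2, 8.82 ± 0.13 in Dox and 10.90 ± 0.09 in E2+Dox. AKR1C2 and AKR1C3 lay 2.28 and 1.61 above Dox alone in E2+Dox, and 3.46 and 3.66 above E2 alone. Between the alternatives AKR1C2 ran from 0.851 to 2.33 against Dox and from 1.4 to 3.56 against E2. AKR1C3 ran from 0.778 to 1.64 and from 1.8 to 3.76. Other genes that lay highest in E2+Dox were the cytokine LIF, at 1.98 above E2 and 1.45 above Dox, the elastic fibre protein FBLN5, at no less than 1.71 and at 1.71, and the protease inhibitor SLPI, at 3.46 and 1.59. AKR1C2, LIF and FBLN5 were named after their values were seen. Members of the AKR1C family share much sequence, so their probe sets are not independent readings.

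A candidate explanation for the AKR1C genes is NRF2, the oxidative stress factor that controls them, and of 24 other NRF2 targets 21 were tested: with Dox 8 rose and 4 fell, with a median change of 0.0857 (camera p = 0.219, and p = 0.523 with an estimated correlation), and with E2 on top of Dox 5 rose and 7 fell, with a median of -0.0566 (p = 0.717, and p = 0.849 with an estimated correlation). Both medians lie far below the rise of the AKR1C genes and argue against a rise of NRF2 targets in general, whereas a partial response to Dox stays open, since GCLM (0.756), ME1 (1.66), SRXN1 (0.523) and PIR (0.788) rose with Dox, 4 genes picked from that list after their values were seen. They also rose with E2 alone (0.533, 1.19, 0.717 and 1.08), and with Dox UGDH (-0.946), GSR (-0.529) and TXNRD1 (-0.130) fell and NQO1 (-0.111) and HMOX1 (-0.190) did not pass. With E2 on top of Dox GCLM (-0.313) and ME1 (-0.417) fell and SRXN1 (-0.057) and PIR (0.132) did not pass, so these 4 give no support for that step.

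The lower level of NF-κB targets in E2+Dox than in Dox could follow from the lower IKBKB level. E2 without Dox also lowered 13 of the 31 targets and raised 5, with a median of -0.164 (camera adjusted p = 0.178). Part of the lower level may thus need no change of IKBKB. The median interaction of these targets was -0.0703, with members that went both ways, so this hypothesis was not decided. Probe sets of the same gene were called in opposite directions in 4.21% (498 of 11838) of cases with E2, 3.95% (412 of 10437) with Dox and 3.37% (300 of 8906) for the interaction, so a change at the brightest probe set does not stand for every transcript of a gene.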
